A study of Mus musculus with 6 samples.

How the data were processed

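RNA was measured in 6 libraries of mouse colon epithelial cells, 3 of Foxo1flox and 3 of VilCre_Foxo1flox mice, which the labels place in groups by title and genotype. Per the labels' protocols, the cells were released from washed colon with EDTA and DTT, and polyadenylated RNA was sequenced. The submitters' processing notes name STAR, Partek and the mm10 build, without versions. The counting tool, the annotation used for counting and the strand setting are not given in the sources used here. The deposited files hold counts, whole numbers of reads per gene for 48526 Ensembl gene identifiers, with no normalization. Another 5 rows per file name no gene (reads outside genes, ambiguous reads, reads aligned to several places and the like). These were left out of library sizes and tests and held 33.0% to 34.9% of all reads in the files. Without a strand setting, reads from overlapping or antisense genes cannot be told apart, and because reads aligned to several places were set aside, near-identical copies such as haemoglobin, Reg3, Oas, Sprr2a, Mcpt and immunoglobulin genes have uncertain counts.

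Symbols and coordinates came from the GENCODE annotation of the same mouse build, in which 48058 identifiers had a symbol. Gene counts per library ranged from 6788167 to 25284820, so that 3 counts, the limit that a count of 0 allows, correspond to 0.119 to 0.442 CPM. Reads carried no molecular identifiers, and such limits and counting intervals cover counting error only.

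Low genes were removed with filterByExpr, libraries were scaled by TMM, and genotypes were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are scaled by TMM. Gene lists, 44 in number, were fixed before the data were examined, and the 39 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with adjustment over the lists. Of the 18 lists called, 9 were also called with an estimated correlation, and the adjusted p under both settings stands beside each result. In 6 lists the median and the mean differed in sign. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, the replicate number as a block, and each replicate left out in turn. Chosen after seeing the data were thinning of libraries to the shallowest total, a test against 1.5-fold change (glmTreat), leaving out mitochondrial genes, and list medians after removal of GC content and length.

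Named genes were the FOXO genes Foxo1, Foxo3, Foxo4 and Foxo6, the 12 with the largest log2 fold change in each direction among called genes with a mean of at least 5 CPM and no overlap between the groups, and up to 4 members with the smallest p in each list with a call or tied to the study's question, predicted gene models being passed over. Some genes that this rule names are not reported here. Further members named in the text, among them those moving against their list, were chosen after their values were seen.

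On simulated data for this comparison with 12502 genes, edgeR recovered 44.9% of 49 genes changed 1.2-fold, 76% of 50 changed 1.5-fold, 92% of 50 changed 2-fold and 100% of 50 changed 4-fold, with 6 false calls among 12303 unchanged genes. The simulation drew genes independently, with the spread of these libraries. That spread may be technical, so the shares do not cover spread between mice. Tests of single values and resampling used scipy 1.17.1 in Python 3.11.15.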

Results

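Gene expression was measured by sequencing of polyadenylated RNA from the colon epithelium of C57BL/6 mice aged 8 weeks, with 3 libraries per genotype. The Foxo1flox group carried loxP-flanked alleles of Foxo1, which encodes a forkhead transcription factor restrained by insulin and PI3K-AKT signalling. The VilCre_Foxo1flox group carried in addition Cre recombinase under the promoter of villin, which is active in intestinal epithelium. Counts assigned to genes totalled 13495161, 25284820 and 19586283 in Foxo1flox replicates 1, 2 and 3, and 9747840, 9803943 and 6788167 in VilCre_Foxo1flox replicates 1, 2 and 3, so the Cre libraries were all shallower. The labels do not say whether the 3 libraries of a genotype came from separate mice, and p-values here measure the spread between these libraries, which may be technical. Between libraries of one genotype, squared differences in counts averaged 2.07 to 2.19 times the variance expected from counting alone in Foxo1flox and 1.42 to 1.54 times in VilCre_Foxo1flox, against 15.3 to 21.3 times between genotypes.

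The targeted gene was examined first. Foxo1 (ENSMUSG00000044167, mm10 chromosome 3, 52268336 to 52353221, plus strand, protein coding) had 250, 478 and 356 counts in the Foxo1flox libraries and 11, 6 and 5 counts in the VilCre_Foxo1flox libraries. Its level fell from 18.5 ± 0.359 CPM (SD, n = 3) to 0.832 ± 0.271 CPM (SD, n = 3), or 4.51% of the floxed level. The log2 fold change was -4.44 with a standard error of 0.20 (edgeR quasi-likelihood test, adjusted p = 8.7e-32). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 against 3 libraries allow. Among the other FOXO genes, Foxo3 rose from 80.0 ± 2.12 to 105.2 ± 3.02 CPM (SD, n = 3), a log2 fold change of 0.39. Foxo4 stood at 35.6 ± 1.22 and 35.8 ± 2.98 CPM (SD, n = 3) and did not pass the test. Foxo6, at 3.25 CPM in Foxo1flox, had a log2 fold change of -0.72 with an edgeR adjusted p of 0.042, which was lost with DESeq2 (adjusted p = 0.12) and with limma-voom (adjusted p = 0.0503), and when Foxo1flox replicate 2 or 3 or VilCre_Foxo1flox replicate 2 or 3 was left out (edgeR adjusted p from 0.077 to 0.20).

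**Figure D1:**
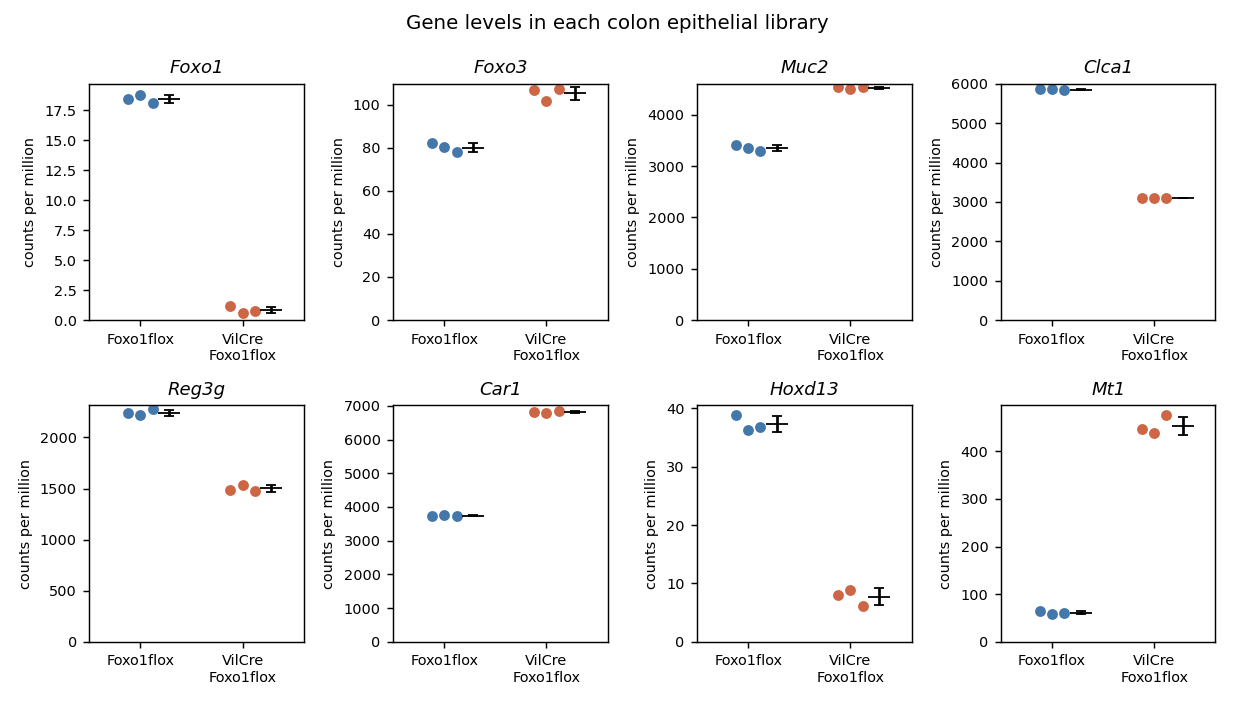
Level of 8 genes in each library, in CPM on linear axes that start at 0; points are libraries, and the horizontal mark and bar beside them give the mean and SD of 3 libraries. Foxo1 lies between 18.1 and 18.8 CPM in Foxo1flox and between 0.618 and 1.14 CPM in VilCre_Foxo1flox.

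The comparison of the genotypes addressed which transcripts differ between colon epithelium with floxed Foxo1 alone and with villin-driven Cre in addition. Of 12617 genes tested, 1500 were higher and 1521 lower in VilCre_Foxo1flox at an adjusted p under 0.05. Most differences were small: the median absolute log2 fold change of the called genes was 0.24, and 56 of the higher and 82 of the lower genes differed by at least 2-fold. Against a null of up to 1.5-fold change, 30 genes were higher and 62 lower. The 3 libraries of one genotype all lay above those of the other for 35.6% of genes tested, where chance gives 10%. Because the residual spread may be technical, these counts do not extend to the spread between mice.

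Called genes with a mean of at least 5 CPM and no overlap between the groups were ranked, predicted gene models being passed over. Of these, the 12 that rose most were Mt1, mt-Rnr2, Rsad2, Sstr1, S100g, Pdk4, Slc10a2, Cmah, Hsph1, Chst11, Mtus2 and mt-Rnr1. Mt1, a metal-binding metallothionein, rose from 61.2 ± 2.93 to 454.2 ± 19.1 CPM (SD, n = 3), a log2 fold change of 2.90. S100g, an intracellular calcium-binding protein, had a log2 fold change of 1.17, and Slc10a2, the ileal bile acid transporter, one of 1.07. Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose from 5.04 ± 1.06 to 10.5 ± 1.45 CPM (SD, n = 3). The call of Mtus2 was lost after thinning to equal depth (edgeR adjusted p = 0.080). Among the genes that fell most in the same ranking were Foxo1, Pnliprp2, Hoxd13, Pla2g4c, Lrg1, Abcg5, Rdx, Ang4, C4bp, Best2 and Sval1. Pnliprp2, a lipase, fell from 21.6 ± 0.605 to 2.36 ± 0.819 CPM (SD, n = 3), a log2 fold change of -3.16. C4bp, which encodes a regulator of complement, had a log2 fold change of -1.25. Abcg5, which encodes one part of a sterol exporter, had a log2 fold change of -1.51, and the phospholipase gene Pla2g4c one of -1.66.

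Goblet cell genes fell as a group. Of 31 tested members of the goblet cell and mucus list, 22 fell, 5 rose and 4 did not pass. Adjusted over the list alone, 22 fell and 5 rose. The median log2 fold change was -0.32 (camera, adjusted p = 5.5e-39, or 0.0029 with an estimated correlation). Clca1, a secreted component of mucus, fell from 5856 ± 11.6 to 3104 ± 3.72 CPM (SD, n = 3). Fcgbp and Tff3, both secreted with mucus, had log2 fold changes of -0.60 and -0.73, and Zg16, a lectin that binds bacteria, one of -0.64. Muc2, the main gel-forming mucin, moved the other way, from 3355 ± 66.3 to 4529 ± 17.3 CPM (SD, n = 3), a log2 fold change of 0.43. The other members that rose were Muc4, Guca2a, Gcnt3 and B3gnt6. The same Cre libraries held a higher share of mitochondrially encoded counts, 3.93% against 2.07%. In the mucin glycosylation list, 11 of 27 tested members fell and 5 rose, or 12 and 6 adjusted over the list alone. The camera call of this list (adjusted p = 0.0067) was lost with an estimated correlation (adjusted p = 0.097). B3gnt7 had the largest fall in that list, from 457.8 ± 10.6 to 209.8 ± 5.24 CPM (SD, n = 3).

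Deep crypt secretory cell genes and antimicrobial genes also fell. Of 9 deep crypt secretory members, 6 fell and 1 rose, or 7 and 1 adjusted over the list alone. Their median was -0.44 (camera, adjusted p = 1.7e-15, or 0.0068 with an estimated correlation). Reg4 and Mptx1 had log2 fold changes of -0.82 and -0.79. In the microbe-induced defence list, 16 of 26 tested members fell and 2 rose, or 17 and 3 adjusted over the list alone. The list median was -0.37 (camera, adjusted p = 1.1e-28, or 0.0094 with an estimated correlation). Ang4 fell from 508.3 ± 5.58 to 197.0 ± 9.64 CPM (SD, n = 3). Reg3g and Reg3b, C-type lectins induced by bacteria, had log2 fold changes of -0.58 and -0.41, and Retnlb, a goblet cell protein, one of -0.86. The members that rose were Tnfaip3 and Duox2. Dissociation and immediate early genes were higher in the same libraries, by a median of 0.44 on the log2 scale. In the Paneth cell and small-intestine antimicrobial list, only 6 of 17 members were expressed enough to be tested. Of these 6, 5 fell, 5 also when adjusted over the list alone. That list had a median of -0.60 (camera, adjusted p = 6.3e-35, or 0.0029 with an estimated correlation). Its members Ang4, Reg3b and Reg3g, 3 in number, also belong to the defence list. The lists share further members: Ang4, Retnlb and Zg16 stand in both the goblet and the defence list. Reads of Reg3 family members and of angiogenin genes can be shared between near-identical copies, so their values are uncertain.

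Genes of absorptive colonocytes rose. Of 25 members, 16 rose and 4 fell, the same numbers when adjusted over the list alone. The median log2 fold change was 0.20 (camera, adjusted p = 2.5e-27, or 0.0029 with an estimated correlation). Car1, a carbonic anhydrase, rose from 3746 ± 22.1 to 6817 ± 35.7 CPM (SD, n = 3), and Krt20, a keratin of differentiated surface cells, from 1021 ± 14.0 to 1365 ± 20.8 CPM (SD, n = 3). Clca4b, Saa1, Lypd8 and Slc37a2 fell. In these libraries T and NK cell genes, dissociation genes and mitochondrially encoded genes had list medians of 0.57, 0.44 and 0.72. Of 17 tested genes of xenobiotic metabolism and the aryl hydrocarbon receptor response, 11 rose and none fell, or 13 adjusted over the list alone. These genes had a median of 0.23 (camera, adjusted p = 7.6e-13, or 0.0075 with an estimated correlation). They included the cytochrome P450 genes Cyp2c55 and Cyp2c65, with log2 fold changes of 0.87 and 0.60, and the efflux pump gene Abcb1a at 0.41. In the fatty acid oxidation and ketogenesis list, 10 of 23 tested members rose and 1 fell, as adjusted over the list alone. Its camera call (adjusted p = 0.00081) was lost with an estimated correlation (adjusted p = 0.25).

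**Figure D2:**
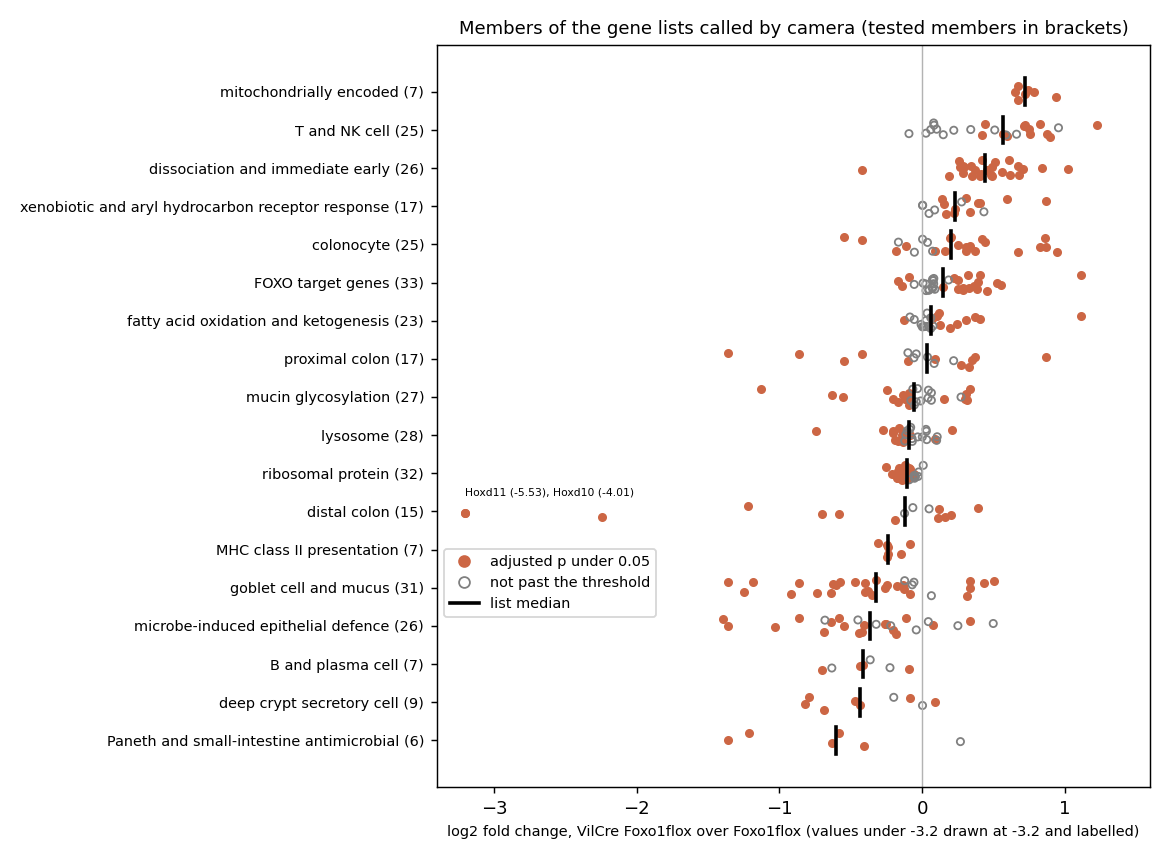
Log2 fold change (VilCre_Foxo1flox over Foxo1flox) of each tested member of the 18 gene lists called by camera; filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians. Most filled points of the goblet list lie left of 0, and Muc2 is among the 5 to the right; Hoxd11 and Hoxd10 lie beyond the axis and are drawn there at its edge, one over the other.

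Genes listed as FOXO targets rose on balance although Foxo1 fell. Of 33 tested, 16 rose and 3 fell, or 18 and 3 adjusted over the list alone, with a median log2 fold change of 0.15 (camera, adjusted p = 1.2e-05; adjusted p = 0.026 with an estimated correlation). Irs2, which encodes an insulin receptor substrate, and Txnip, a regulator of thioredoxin, had log2 fold changes of 0.53 and 0.29. Klf4, Pink1 and Tnfsf10 fell. Klf2 and Klf6 also stand in the dissociation list, and without both, 14 of 31 members rose and 3 fell, with a median of 0.09. Of 38 autophagy genes, 2 rose and 3 fell, or 2 and 1 adjusted over the list alone, and the list was not called (camera, adjusted p = 0.90). Of 23 tight junction and adhesion genes, 6 rose and 5 fell, as adjusted over the list alone (camera, adjusted p = 0.79), and Cldn8 fell from 233.2 ± 13.1 to 123.5 ± 1.76 CPM (SD, n = 3).

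Markers of position along the colon were mixed. In the distal colon list, 7 of 15 tested members fell and 5 rose, as adjusted over the list alone, and the camera call (adjusted p = 1.7e-05) was lost with an estimated correlation (adjusted p = 0.080). Hoxd13 (mm10 chromosome 2, 74668310 to 74671599), a homeobox gene of the posterior body, fell from 37.3 ± 1.39 to 7.70 ± 1.47 CPM (SD, n = 3), and Hoxb13 had a log2 fold change of -0.58. Hoxd11 had 130 counts summed over Foxo1flox and 1 over VilCre_Foxo1flox, a ratio of CPM of 58.7 with a 95% exact interval, for counting error alone, of 10.3 to 2335. In the same list Aqp4, Aqp8 and Ces1f rose. Aqp4 and Aqp8 also stand in the colonocyte list and Ces1f in the xenobiotic list, both of which rose, so they are not markers of position alone. The other distal members that rose, Slc16a1 and Hao2, had log2 fold changes of 0.11 and 0.12. In the proximal colon list, 6 of 17 members rose and 5 fell, or 7 and 6 adjusted over the list alone. Its median was 0.04, its mean -0.05 and its camera direction down (adjusted p = 0.048), a call lost with an estimated correlation (adjusted p = 0.25), with the replicate block (adjusted p = 0.060), with a filter at 5 CPM (adjusted p = 0.089) and when Foxo1flox replicate 1 or 2 or any one VilCre_Foxo1flox replicate was left out (adjusted p from 0.053 to 0.14).

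**Figure D3:**
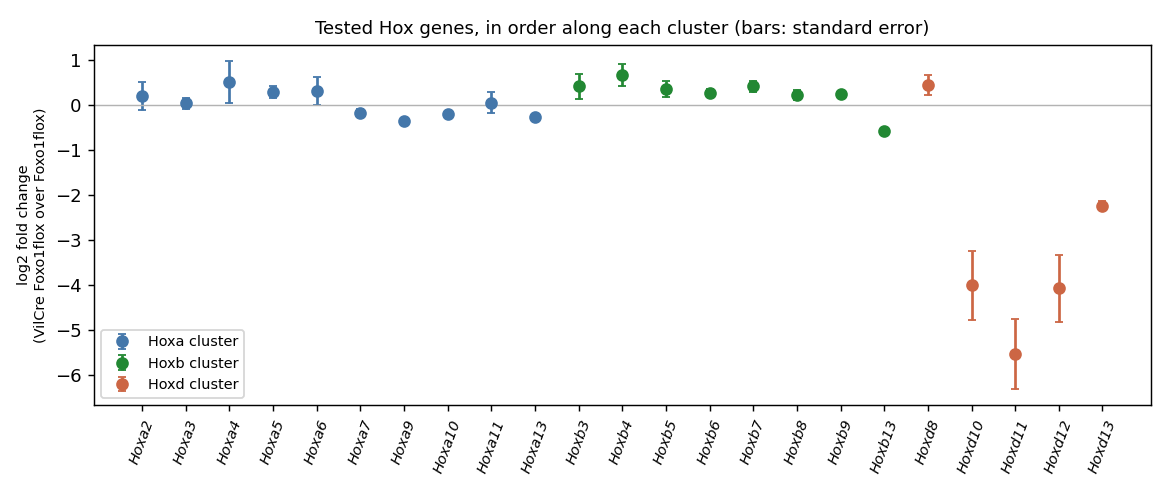
Log2 fold change (VilCre_Foxo1flox over Foxo1flox) of the 23 tested Hox genes, a set chosen after their values were seen, in order along the Hoxa, Hoxb and Hoxd clusters; bars are standard errors. Hoxd10, Hoxd11 and Hoxd12 have 1 or 2 summed counts in VilCre_Foxo1flox, so their fitted values depend on the prior count.

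Signs of RNA origin and markers of other cells moved with genotype in the same libraries as the groups above. Of 26 tested genes of tissue dissociation and the immediate early response, 25 rose and Socs3 fell, as adjusted over the list alone. Their median log2 fold change was 0.44 (camera, adjusted p = 4.8e-60, or 0.0029 with an estimated correlation). Fosb and Egr1 had log2 fold changes of 0.84 and 0.71, and the heat shock gene Hsph1 one of 1.02. Mitochondrially encoded genes took 2.07 ± 0.0648% of gene counts in Foxo1flox and 3.93 ± 0.0345% in VilCre_Foxo1flox (SD, n = 3). All 7 of 7 tested messenger RNAs of this list rose, as adjusted over the list alone, with a median of 0.72. Camera gave this list an adjusted p of 1.2e-130 at the preset correlation, and of 0.0029 with the estimated correlation of 0.71. Of 32 ribosomal protein genes, 24 fell and none rose, or 26 adjusted over the list alone, a camera call (adjusted p = 1.9e-08) lost with an estimated correlation (adjusted p = 0.21). Of 25 T and NK cell genes, 12 rose and none fell, or 13 adjusted over the list alone, a camera call (adjusted p = 0.00051) lost with an estimated correlation (adjusted p = 0.10). Among them Gzma rose from 15.0 ± 0.851 to 25.4 ± 0.971 CPM (SD, n = 3). Of 7 tested B and plasma cell genes, 4 fell, as adjusted over the list alone, a call (camera, adjusted p = 0.015) lost with an estimated correlation (adjusted p = 0.17). Igha, the constant region of immunoglobulin A, had a log2 fold change of -0.41.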

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

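The tests in this part were all chosen after the results were seen. Reads outside the gene counts differed between the genotypes. Uniquely aligned reads that fell outside any gene made up 3.38 ± 0.0375% (SD, n = 3) of unique reads in Foxo1flox and 4.0 ± 0.00962% (SD, n = 3) in VilCre_Foxo1flox. Reads aligned to several places made up 28.2 ± 0.101% (SD, n = 3) and 29.61 ± 0.0499% (SD, n = 3) of all reads. For both measures, each of the 3 Cre libraries lay above each of the 3 floxed libraries.

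Libraries of one genotype differed far less than libraries of different genotypes, and whether those of one genotype share one RNA source was left open by the tests. Immunoglobulin variable segments, whose use differs between animals, varied within a genotype 0.95 times (Foxo1flox) and 0.87 times (VilCre_Foxo1flox) as much as other genes of like count, in line with a shared source or pooled mice. The 39 segments held 1155 and 300 counts, too few to decide. Within a genotype, the upper 95% limit of their coefficient of variation was 1.31 times (Foxo1flox) and 1.29 times (VilCre_Foxo1flox) the lower limit between genotypes. By these segments, separate mice and one source cannot be told apart. This comparison took 3 forms in turn: an earlier one, by pairs of libraries, was dropped because VilCre_Foxo1flox pairs held too few segments with enough counts, and a later one, tried because the segments did not decide, used 42 genes of the dissociation and defence lists, whose coefficient of variation beyond noise was at most 1.82% and 1.89% (upper 95% limits) within the genotypes and 24.6% between them. As those lists were themselves called between the genotypes, the 24.6% decides nothing. The limits within the genotypes do not rest on those calls. They argue against separate mice that differ by more than these limits in these 42 genes. Over all genes tested, the common coefficient of variation beyond counting noise fitted by edgeR was 2.63%. One source, pooled mice and separate mice as alike as this were not told apart.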

How the results depend on the processing

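Thinning, the test against 1.5-fold change and the fit without mitochondrial genes were chosen after the data were seen. The Foxo1 level kept its direction and its call in the 17 alternatives run, with log2 fold changes from -4.77 to -4.23. No call of a gene tested in both fits changed sign in any alternative. Against a null of up to 1.5-fold change, 30 genes were higher and 62 lower, since that test asks for a larger change. The other counts stayed within 1.5 times of 1500 higher and 1521 lower: DESeq2 gave 1060 and 1056, limma-voom 1464 and 1406, thinning to equal depth 1153 and 1197, and leaving out one replicate 1142 to 1376 and 1209 to 1413. Library totals as the scaling gave 1268 and 1751, a share of higher calls of 42.0% against 49.7%. Camera called 18 lists, and 9 with an estimated correlation. A correlation above the preset 0.01 does not account for every loss. The lysosome and mucin glycosylation lists lost their calls at estimates of -0.021 and 0.0037, while the other lists that lost theirs had estimates above 0.01. The cause was not tested further. The fry test, which does not compare a list with other genes, called 26. Whether replicate numbers pair the samples stays open. Deviations of libraries with the same number correlated at -0.005, -0.021 and -0.014, and those with different numbers at -0.009 to 0.025. Counting noise makes up much of the spread within a genotype, so values near 0 could arise with pairing too. With the replicate block 1439 genes were higher, 1455 lower and 17 lists called. Over the named genes, 170 values lost their call and 5 gained one across the alternatives, 121 of the losses under the 1.5-fold test. Depth limits the number of calls, as the thinned libraries gave fewer.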

Other observations

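All tests in this part other than the list tests were chosen after the results were seen, and those on goblet cell number and metal induction replaced earlier ones that could hardly have come out otherwise. Of 46 interferon response genes, 13 rose and 17 fell, or 14 and 17 adjusted over the list alone: Rsad2, an antiviral protein, rose from 6.44 to 14.8 CPM, and Iigp1, an interferon-inducible GTPase, had a log2 fold change of -0.76. The 7 tested genes of MHC class II presentation fell, as adjusted over the list alone, among them H2-Ab1 at -0.31, a call (camera, adjusted p = 1.2e-05) lost with an estimated correlation (adjusted p = 0.081). In the same libraries 4 of 7 B and plasma cell genes fell, with a list median of -0.41, and of 17 tested myeloid genes 4 fell and 2 rose, as adjusted over the list alone, with a median of -0.16 (camera, adjusted p = 0.41). Of 28 lysosome genes, 12 fell and 2 rose, or 15 and 2 adjusted over the list alone (camera, adjusted p = 0.0036; adjusted p = 0.080 with an estimated correlation). In the inflammasome list, 3 of 15 rose and 4 fell, as adjusted over the list alone, and Il18 had a log2 fold change of -0.56. Of 30 proliferation genes, 8 rose and 16 fell, or 8 and 17 adjusted over the list alone (camera, adjusted p = 0.17): Mcm6 and Mcm7, parts of the replicative helicase, had log2 fold changes of 0.24 and 0.27, and the mitotic genes Ccnb1 and Ube2c -0.32 and -0.33. The 4 tested haemoglobin genes rose, with Hbb-bs at 0.90, in a list too short for camera.

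Goblet and defence genes were lower in VilCre_Foxo1flox. The 5 most abundant goblet-list members that stand in no other list had log2 fold changes from -0.92 for Clca1 to 0.43 for Muc2. They differed by up to 1.35, which goes against a fall in goblet cell number as the whole cause for these 5 genes. The bounds of this test were set when the values were known, so it gives no independent support. Sampling nearer the caecum in the Cre mice stays open: distal and proximal list members, without Hox, goblet and defence genes, differed in median by -0.036 (11 members each, 95% bootstrap interval -0.45 to 0.21), while Ang4, Retnlb and Saa1, defence genes that also stand in the proximal colon list and that this explanation would raise, fell, with log2 fold changes of -1.36, -0.86 and -0.42, and Fut2, also in both lists, had -0.04 and did not pass. The fall of posterior Hox genes, at first taken as the test, was set aside because this set of 8 was picked after Hoxd13 had been seen to fall. Hoxd10, Hoxd11, Hoxd13 and Hoxb13 nevertheless stood in the distal list fixed beforehand, and all fell. In the proximal list Hoxb6 rose, by 0.27, and Hoxb8 did not pass. These changes go with a position difference. Of the 8 posterior genes 7 fell, by most in the neighbouring Hoxd10 to Hoxd13. The fall was less in Hoxa10, Hoxa13 and Hoxb13 (log2 fold changes -0.21, -0.27 and -0.58), while of 15 other Hox genes 4 rose and 1 fell. Loss of Foxo1, with a goblet list median of -0.321, cannot be told apart from position or from any other difference between the groups, Cre itself included. Genotype is the only grouping, no libraries are matched for position, and no group carries Cre without floxed Foxo1.

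Mt1 rose far more than its neighbour Mt2. The log2 fold change of Mt1 exceeded that of Mt2 by 2.01 (standard error 0.105), and Mt2 itself rose, by 0.89. Induction by metal or stress stays open: the zinc exporter gene Slc30a1, a zinc-responsive gene outside the pattern, rose by 0.18, too little to decide. A candidate explanation is that reads of a metallothionein sequence in the Cre transgene were counted on Mt1, whose lowest Cre library stood 6.81 times above the highest floxed library. This stays open, because the sources used here do not say what the transgene holds and counts per gene do not place reads along it.

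Of the 10 splits of the 6 libraries into groups of 3, the real one (1 of 10) called 3021 genes and the highest other 0, and the real one (1 of 10) called 18 lists and the highest other 11. With 10 splits no share under 0.05 can be reached. Every other split also mixed the genotypes within its groups, which widens their spread, so its lack of gene calls could be foreseen and gives no support.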
